A study of Mus musculus with 8 samples.

How the data were processed

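Total RNA of sorted bone marrow cells of adult C57BL/6 mice was amplified from a few nanograms with the Ovation Pico system, labelled with biotin and hybridised to 1-colour Affymetrix MouseGene ST arrays, per the labels' protocols. The protocol names 2 versions of that array (1.0st and 2.0st) and does not say which sample went on which. The deposited table holds log2 values for 24973 probe sets on 8 arrays, and RMA and Partek are named without versions per the submitters' processing notes. Genome build, probe set definition and any pooling of samples are not given in the sources used here. The scale was read from the values, which run from 1.66 to 13.1. No detection calls come with the table.

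Each probe set carries 1 Entrez gene ID. A table of probe names gave 1 symbol for 24015 probe sets, several for 0 and none for 958, which are unnamed here. For 23922 of the named ones the symbol was updated by Entrez gene ID through a RefSeq gene table (GRCm38.p6), which was used for names only because the build behind the deposited table is not stated. Where a symbol had more than 1 probe set, the brightest over all 8 arrays was kept, which left out 4 and gave 24011 genes. All 8 arrays were mapped to samples by their labels, 4 Lin+ and 4 HSC-enriched.

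Differences are HSC-enriched minus Lin+ means of the deposited log2 values, tested with limma 3.58.1 (lmFit and eBayes, R 4.3.3) in a 2-group model without covariates and adjusted by Benjamini-Hochberg over all genes. The threshold was an adjusted p of 0.05, with a 2-fold minimum where stated. Standard errors are limma's, and adjusted p-values without another name are from this test. No filter on low values was applied in the main fit. Lists were tested with limma's camera at its preset inter-gene correlation of 0.01, two-sided, adjusted over 35 lists, and adjusted p-values of lists are from camera. Camera with an estimated correlation and fry were run beside it. At an adjusted p of 0.05, fry, which does not compare a list with other genes, found 31 lists moving on balance one way. Of 712 list entries 668 were measured, and the others were not analysed here. Olfactory receptor genes served as a guide to background.

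Design, tests, lists, rule for named genes and alternatives were chosen before the data were examined. The rule took, in each direction, the 14 genes with the largest fitted difference among those with an adjusted p under 0.05 and no overlap between the groups. It left out predicted or unnamed loci, small RNAs, olfactory and vomeronasal receptors and antigen receptor segments. It further took every gate antigen and, in each other list, up to 2 passing members with the largest rise, up to 2 with the largest fall and up to 2 not passing with the highest level. This gave 178 genes.

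The alternatives were centring each array on its median, quantile normalization again, and filters at the 40th percentile or the median of all values on at least 4 arrays. Others were the mean of a gene's probe sets, every probe set, eBayes with a trend and robust estimates, array weights, the replicate number as a block, a test against a 1.2-fold null, an estimated correlation and each array left out in turn. Leaving out HSC-enriched replicates 3 and 4 together was added after seeing the data. The labels number replicates 1 to 4 in both groups, and no batch or date is given. The samples are listed as Lin+ replicates 1 to 3, HSC-enriched replicates 1 and 2, Lin+ replicate 4 and HSC-enriched replicates 3 and 4. Whether that order reflects separate processing is not stated, and the replicate number as a block would not capture it. No 2 arrays held the same values: the SD of the difference between arrays of 1 group was 0.334 to 0.421.

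The fit was tested on simulated data for the 24011 genes of this comparison, with 200 genes changed. It recovered 13.4% of those changed 1.41-fold, 91.0% of those changed 2-fold and 97.0% of those changed 4-fold. The fit called 172 genes in all, of which 26 belonged to the lists shifted 1.41-fold and 12 were unchanged. In the real data 6685 genes passed, so the unadjusted p needed to pass was less strict there. The recovered shares therefore do not give the sensitivity of the real comparison. Camera found 10 of 10 shifted lists and 0 of 10 unshifted ones, in data simulated without correlation between genes. Figures were drawn with matplotlib 3.10.9 (Python 3.11.15).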

Results

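Gene expression was measured in adult bone marrow of C57BL/6 mice in 2 sorted cell populations. Lin+ cells, which carry surface markers of mature blood lineages, were hybridised to 4 arrays. HSC-enriched cells, a rare population in which haematopoietic stem cells (HSCs) are concentrated, were hybridised to another 4. The sample labels describe the HSC-enriched cells as LSK cells (lineage-negative, Sca-1-positive, Kit-positive) positive for CD105 and negative for CD48, whereas the series' design text names CD150 where the labels name CD105. The values are log2 levels of 24973 probe sets, of which 24011 named genes were tested. Array medians ran from 5.22 to 5.33. Correlations across genes, which are not independent replicates, were 0.981 to 0.986 between Lin+ arrays, 0.978 to 0.986 between HSC-enriched arrays and 0.893 to 0.922 between the groups. The labels do not say that the samples came from separate animals, so p-values measure only the spread between these samples, which may be technical, and 4 arrays per group limit the precision.

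The comparison of HSC-enriched with Lin+ cells asks which transcripts set the stem cell population apart from maturing marrow cells. Myct1 had the highest fitted difference under the rule for named genes, at 10.35 ± 0.22 in HSC-enriched against 4.71 ± 0.58 in Lin+ cells (log2, SD, n = 4), a 49.7-fold difference (adjusted p = 3.1e-07) with the Lin+ mean near background. Angpt1, which encodes a ligand of the Tek receptor, was 37.3-fold higher, and the transcription factor genes Meis1, Hlf and Mecom were 22.6-, 20.2- and 17.7-fold higher. In the other direction, Klk1 fell from 9.95 ± 0.22 to 3.18 ± 0.60 and the beta-globin gene Hbb-bs from 11.11 ± 0.39 to 4.40 ± 1.72, or 109-fold and 105-fold. Genes of B cells and plasma cells (Igha, Ighm, Spib, Ms4a1) and of granulocytes (Ly6g, Mpo, Elane, Prg2) were 43.2-fold to 82.4-fold lower.

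In total, 3716 genes were higher and 2969 lower in HSC-enriched cells (limma, Benjamini-Hochberg adjusted p under 0.05), of which 1153 and 1461 differed by at least 2-fold. Large differences were mostly losses: 58 genes were at least 8-fold higher against 365 at least 8-fold lower, and 14 against 164 at least 16-fold. The 4 arrays of one group lay entirely above the 4 of the other for 6943 genes, 28.9% of those tested, where chance gives 2.86%. The other genes of the 14 with the largest rise were Ctla2b, Bex1, Adgrl4, Gucy1a1, Ccl19, Emcn, Gng11, Muc13 and Trpc6, with differences of 4.04 (Trpc6) to 4.94 (Ctla2b). The remaining genes of the 14 with the largest fall were Ifi209, H2-DMb2, Stfa2l1 and Clec12a, with differences of -5.79, -5.69, -5.51 and -5.50. Stfa2l1 had a standard error of 1.16, since its HSC-enriched arrays spread with an SD of 2.98. Many small values lay near background: the 1074 olfactory receptor genes, used as a guide, had a 95th percentile of 5.10, 577 of the 2-fold lower genes had an HSC-enriched mean at or under it, and 368 of the 2-fold higher genes a Lin+ mean at or under it. Folds of these genes, and their rank by fold, rest on values near background. Among the 14 with the largest rise this holds for Myct1, Ctla2b, Gucy1a1, Ccl19, Emcn, Mecom and Trpc6, and among the 14 with the largest fall for all but Ighm, Stfa2l1, Mpo and Elane. Single arrays of Stfa2l1 and Elane lay under the guide too. Stfa2l1 was at 3.45 and 2.85 on HSC-enriched replicates 1 and 2, against 7.90 and 8.63 on replicates 3 and 4. Elane was at 4.61, 4.53 and 5.02 on replicates 1, 2 and 4, against 6.59 on replicate 3.

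**Figure D1:**
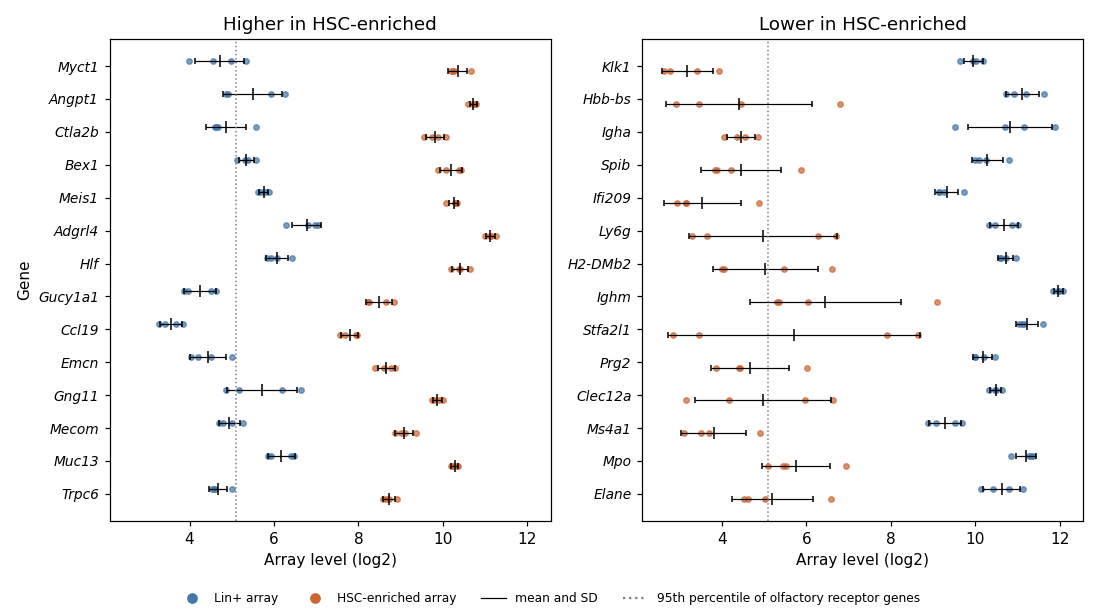
Array levels (log2) of the 14 genes with the largest rise (left) and the 14 with the largest fall (right) under the rule for named genes, with each point 1 array (blue Lin+, orange HSC-enriched), bars mean and SD over 4 arrays, and the dotted line the 95th percentile of olfactory receptor genes (5.10). The groups do not overlap for any of the 28 genes plotted, and Stfa2l1 shows the widest HSC-enriched spread (SD 2.98).

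The measured antigens of the gate followed the sort, whereas Ly6a, which encodes Sca-1, was not measured. Kit (Entrez gene 16590) was 10.44 ± 0.07 against 7.24 ± 0.24, Eng (13805), which encodes CD105, 9.61 ± 0.09 against 6.65 ± 0.11, and Slamf1 (27218), which encodes CD150, 7.17 ± 0.15 against 5.37 ± 0.09, each higher in HSC-enriched cells. Cd48 (12506) fell from 8.65 ± 0.32 to 4.96 ± 0.16, a 12.9-fold difference. All 4 measured antigens passed the test, over all genes and adjusted over the list alone. Kit and Cd48 were used to sort the cells by both sources, Eng by the sample labels and Slamf1 by the design text. Genes used to sort are no independent result, and which of Eng and Slamf1 was used is not settled. As a list they were called higher (median 2.38, camera adjusted p = 0.019), but not with an estimated correlation (adjusted p = 0.095) or with the filters at the 40th percentile and the median (0.066 and 0.084).

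Genes known from HSCs were higher as a group. Of 38 measured, 33 rose, 2 fell and 3 did not pass, with a median difference of 2.06, and 34 rose and 3 fell when adjusted over the list alone. Besides Angpt1 and Meis1, the list holds Hoxa9, at 8.95 ± 0.18 against 5.63 ± 0.30. Thy1 fell by 1.33 and Ifitm1 by 1.21, the latter losing its call when any of 5 single arrays was left out (adjusted p = 0.0505 to 0.077). Ly6e (-0.19) and Gfi1 (-0.39) did not pass. Gfi1 did without Lin+ replicate 4 (-0.51, adjusted p = 0.046) or HSC-enriched replicates 3 and 4 together (-0.61, adjusted p = 0.037). The list's call (camera adjusted p = 3.5e-21) held with an estimated correlation (adjusted p = 0.00095). Over the 35 lists, 7 were called higher and 14 lower with the preset correlation, and 2 and 4 with an estimated one. When the 8 arrays were split with 2 of each group on either side, the preset test called at most 4 lists one way.

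Homeobox genes of the Hoxa and Hoxb clusters moved the same way: 11 of 19 rose and 0 fell, over all genes and adjusted over the list alone, with a median of 0.70, or 1.27 with genes above the median of all values on 4 arrays. Hoxa9 and Hoxa5 rose 9.99-fold and 8.95-fold, while Hoxa4 (0.40) and Hoxa11 (-0.10) did not pass. The list was called with the preset correlation (adjusted p = 9.6e-06) and with an estimated one (adjusted p = 0.027). Among Wnt signalling genes 14 of 25 rose and 1 fell (15 and 1 adjusted over the list alone). The receptor genes Fzd8 and Ryk rose 6.00-fold and 5.90-fold, and Lef1, a transcription factor of the pathway that is active in lymphocytes, fell 7.07-fold. Axin1 (0.20) and Dvl2 (0.33) did not pass, though Dvl2 did without Lin+ replicate 3 (0.42, adjusted p = 0.015) and with both filters. The Wnt list's median was 0.65 (adjusted p = 5.7e-05), with adjusted p = 0.069 with an estimated correlation. Of 21 imprinted genes, 9 rose and 1 fell (10 and 1 adjusted over the list alone), led by Grb10 (12.2-fold) and Sgce (3.76-fold), whereas Igf2r fell by 0.61 and Peg12 (0.16) and Snrpn (-0.31) did not pass. Their median was 0.39 (adjusted p = 0.00078), with adjusted p = 0.114 with an estimated correlation.

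Transcripts of B cells, neutrophils, erythroid cells and monocytes were lower in HSC-enriched cells, most of all those of B cells and neutrophils. All 21 measured B cell genes fell (median -4.48), led by Spib, a transcription factor gene, and Ms4a1, which encodes CD20. Of 27 neutrophil genes 26 fell (median -4.12), led by Ly6g (51.8-fold) and Mpo (43.7-fold); S100a8, at 11.30 ± 1.31 against 12.70 ± 0.07, did not pass (adjusted p = 0.071), though it did with both filters and without HSC-enriched replicate 3 (-1.74, adjusted p = 0.028) or 4 (-1.80, adjusted p = 0.018). Erythroid genes fell in 21 of 22 cases (median -2.67), with Slc4a1, the band 3 anion exchanger, 18.5-fold lower after Hbb-bs, and Car2, a carbonic anhydrase gene, 1.52-fold higher. Of 23 monocyte and macrophage genes 21 fell (median -2.64), led by Ccr2 (34.3-fold) and Ly86 (28.9-fold), while Klf4 (0.26) and Ly6c1 (-0.71) did not pass. Ly6c1 passed with the replicate block and without Lin+ replicate 1 (-0.93, adjusted p = 0.015) or HSC-enriched replicate 3 (-0.94, adjusted p = 0.012). Adjusted over the list alone, the falling genes numbered 21 for B cells, 27 for neutrophils, 21 for erythroid cells and 22 for monocytes. Each of these lists was called lower with the preset correlation (adjusted p = 1.8e-21, 1.0e-18, 3.0e-18 and 2.5e-18 in the same order). None of the calls held with an estimated correlation (adjusted p = 0.072, 0.114, 0.084 and 0.056).

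HSC-enriched arrays were unequal in these same transcripts. The mean level of the neutrophil genes was 6.38 and 6.27 on HSC-enriched replicates 1 and 2 but 8.30 and 8.14 on replicates 3 and 4, against 11.03 ± 0.17 on Lin+ arrays. Ngp, a neutrophil granule gene, was at 8.64, 8.37, 12.00 and 11.98 on the same 4 arrays. The B cell genes averaged 5.89 on replicate 3 against 4.79, 4.79 and 4.93 on replicates 1, 2 and 4, and the monocyte genes 5.84 against 5.28, 5.13 and 5.47. Without replicates 3 and 4, an alternative chosen after seeing the data, 27 neutrophil genes fell with a median of -5.25, and B cell, erythroid and monocyte genes fell in 21, 21 and 22 cases. S100a8 then fell by 2.52.

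**Figure D2:**
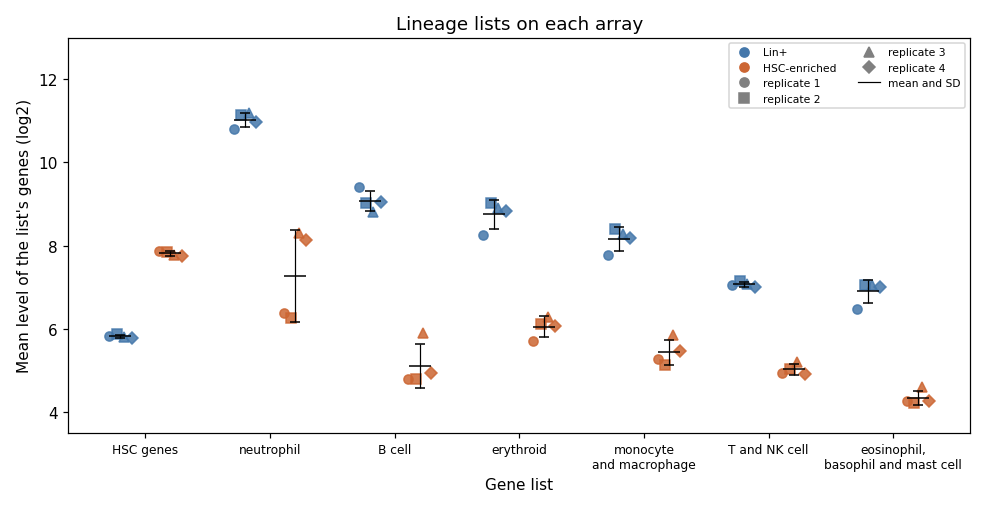
Mean log2 level of the genes of 7 lists on each array (vertical axis), with blue symbols for Lin+ and orange for HSC-enriched arrays, symbol shape for the replicate number, and bars for mean and SD over 4 arrays. Neutrophil genes stand at 8.30 and 8.14 on HSC-enriched replicates 3 and 4 and at 6.38 and 6.27 on replicates 1 and 2, whereas the HSC genes lie between 7.75 and 7.88 on all 4.

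Other immune genes were lower too, and these lists kept their calls with an estimated correlation. Of 23 T and NK cell genes 20 fell (median -1.70, adjusted p = 3.8e-16, and adjusted p = 0.0066 with an estimated correlation), with Cd2 and Klrd1 27.6-fold and 18.4-fold lower and Cd28 (0.26) and Klrb1c (-0.31) not passing. All 12 genes of eosinophils, basophils and mast cells fell (median -2.15, adjusted p = 1.4e-11, and adjusted p = 0.037 with an estimated correlation), led by Prg2, eosinophil major basic protein, and Mcpt8, a basophil protease gene. Of 13 dendritic cell genes 8 fell (median -1.77, adjusted p = 1.2e-07, and adjusted p = 0.033 with an estimated correlation), led by Klk1 and Ly6d, whereas Bst2 (-0.58) and Tcf4 (-0.07) did not pass. Bst2 passed without HSC-enriched replicate 1 (-0.71, adjusted p = 0.028) and in 4 other alternatives. Of 10 genes of MHC class II, which presents antigen to T cells, 8 fell (median -1.96, adjusted p = 7.3e-07, and adjusted p = 0.037 with an estimated correlation). H2-DMb2 and Cd74 were 51.5-fold and 6.55-fold lower, and H2-DMa (0.13) and H2-DMb1 (-0.26) did not pass. Adjusted over the list alone, 21 T and NK, 12 eosinophil, basophil and mast cell, 9 dendritic and 8 MHC class II genes fell. On HSC-enriched replicate 3 the T and NK genes averaged 5.21 and the eosinophil, basophil and mast cell genes 4.59, against 4.94 and 4.25 on replicate 1.

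Genes of progenitors and of haem synthesis were lower with fewer exceptions among the latter. Of 14 progenitor genes 10 fell and 3 rose, over all genes and adjusted over the list alone (median -1.23, adjusted p = 8.2e-05, and adjusted p = 0.056 with an estimated correlation). Il7r, the receptor gene of lymphoid progenitors, fell 42.5-fold together with Mpo, while Cd34 and Cd27 rose 8.42-fold and 6.08-fold and Flt3 (-0.07) did not pass. As drawn up, the list shares Mpo with the neutrophil, Klf1 with the erythroid, Irf8 with the monocyte and Dntt with the B cell list. It also shares Flt3 with the dendritic cell list. Its fall is therefore in part the same result as that of the mature lineages. The progenitor genes averaged 7.01 on HSC-enriched replicate 3, 0.21 above the next array. Of 14 haem synthesis genes 13 fell, over all genes and adjusted over the list alone (median -1.17, adjusted p = 1.1e-09, and adjusted p = 0.114 with an estimated correlation), with Alas2 and Alas1, the enzymes of the first step, 14.6-fold and 3.37-fold lower and Slc25a39 (0.08) not passing.

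Genes of mitosis were lower without exception. All 26 fell, over all genes and adjusted over the list alone, with a median of -1.27 (adjusted p = 1.3e-19, and adjusted p = 0.056 with an estimated correlation). Plk1, a mitotic kinase gene, was 7.33 ± 0.48 against 9.25 ± 0.08, and Ube2c was 3.39-fold lower. DNA replication genes were mixed: 8 of 26 fell and 3 rose (9 and 3 adjusted over the list alone). Rrm2 and Ccne1 fell 5.62-fold and 2.94-fold, Chaf1b and Mcm6 rose 1.80-fold and 1.42-fold, and Pcna (0.16) and Rrm1 (-0.30) did not pass. Rrm1 passed without Lin+ replicate 1 (-0.34, adjusted p = 0.041) and in 4 other alternatives, and Pcna with quantile normalization (0.35, adjusted p = 0.026). The median of the replication genes was -0.26 (adjusted p = 0.020, and adjusted p = 0.485 with an estimated correlation), and the call was lost with the filter at the median (adjusted p = 0.056) and without HSC-enriched replicate 4 (median -0.14, adjusted p = 0.072), Lin+ replicate 2 (median -0.19, adjusted p = 0.064) or HSC-enriched replicates 3 and 4 together (median -0.13, adjusted p = 0.148). Cyclin-dependent kinase inhibitors and pocket proteins went both ways, with 5 of 14 higher and 6 lower in both adjustments and no call (median -0.18, adjusted p = 0.245). Cdkn1a and Cdkn1c rose 2.70-fold and 2.20-fold, Cdkn2c and Rb1 fell 3.75-fold and 2.81-fold, and Tob1 (-0.18) and Cdkn2b (0.12) did not pass.

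Receptor and response genes differed gene by gene. Of 21 cytokine receptor genes 12 fell and 6 rose in both adjustments (median -0.69, adjusted p = 0.0013, and adjusted p = 0.095 with an estimated correlation). Tek, the angiopoietin receptor gene, rose 7.93-fold and Csf1r, the receptor gene of the macrophage growth factor, fell 10.9-fold, while Ifnar1 (-0.15) and Il3ra (-0.24) did not pass. Of 25 immediate-early and stress genes 11 rose and 2 fell (13 and 3 adjusted over the list alone). The nuclear receptor genes Nr4a2 and Nr4a1 rose 9.64-fold and 7.98-fold, Btg2 and Ier5 fell by 0.64 and 0.51, and Zfp36 (0.32) and Dusp1 (-0.30) did not pass. Ier5 lost its call with the replicate block and without Lin+ replicate 2 (-0.45, adjusted p = 0.084) or 4 (-0.50, adjusted p = 0.067). Its call was also lost without HSC-enriched replicates 3 and 4 together (-0.35, adjusted p = 0.131). Zfp36 passed with a trend and robust estimates and without Lin+ replicate 1 (0.38, adjusted p = 0.0499). The median of the immediate-early and stress list was 0.76 (adjusted p = 0.0091, with 0.538 for an estimated correlation and 0.060 for the filter at the median) and 0.29 without Lin+ replicate 4, whose genes of this list averaged 8.10 against 8.75 to 9.16 on the other Lin+ arrays. Interferon response genes fell in 11 of 23 cases and rose in 4 (11 and 5 adjusted over the list alone), with Rsad2 and Cmpk2 2.95-fold and 2.17-fold lower, Gbp2 and Gbp3 2.21-fold and 2.16-fold higher, and Ifi27 (0.10) and Rtp4 (-0.01) not passing. Their call (median -0.38, adjusted p = 0.047) was lost without Lin+ replicate 2, Lin+ replicate 4 or HSC-enriched replicate 4 (adjusted p = 0.060, 0.079 and 0.086; medians -0.27, -0.30 and -0.44). It was also lost with centring (0.054), the filters at the 40th percentile (0.072) and the median (0.091), a trend and robust estimates (0.052), array weights (0.051), HSC-enriched replicates 3 and 4 left out (0.060) and an estimated correlation (0.305).

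Endothelial genes split. Of 15, 6 rose and 1 fell (6 and 2 adjusted over the list alone), with Emcn 18.6-fold and Tie1 9.01-fold higher and Pecam1 lower by a fold of 1.28, while Cdh5 (-0.36) and Kdr (0.30) did not pass. The Pecam1 call was lost with quantile normalization (adjusted p = 0.051), with the replicate block (0.071) and without Lin+ replicate 2 (0.078), HSC-enriched replicate 1 (0.071), HSC-enriched replicate 2 (0.068) or HSC-enriched replicates 3 and 4 together (0.066). The list was called higher (median 0.30, adjusted p = 0.0027, and adjusted p = 0.095 with an estimated correlation), and its median was 0.19 without HSC-enriched replicate 1 and 0.46 without HSC-enriched replicate 2. With genes above the 40th percentile on 4 arrays its median was 0.97, and with genes above the median 2.09.

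None of the other 13 lists was called, although several held members that moved at least 2-fold in each direction. Megakaryocyte and platelet genes rose in 9 of 20 cases and fell in 2 (adjusted p = 0.070, median 0.16), with Gp9 and Vwf, of the platelet adhesion system, 4.39-fold and 4.26-fold higher, Thbs1 and Plek 6.23-fold and 1.99-fold lower, and Fli1 (0.00) and Nfe2 (0.04) not passing. This list passed without Lin+ replicate 4 (median 0.46, adjusted p = 0.046), HSC-enriched replicate 3 (0.20, adjusted p = 0.041) or HSC-enriched replicates 3 and 4 together (0.25, adjusted p = 0.030). TGF-beta and BMP genes rose in 10 of 28 cases and fell in 5 (adjusted p = 0.051, median 0.15), led by Eng and Tgfbr3 (6.77-fold) and by Id2 (4.31-fold lower) and Acvrl1 (2.52-fold lower), with Tgfb1 (-0.24) and Smad2 (0.14) not passing, and passed with centring (0.045), with array weights (0.044) and without Lin+ replicate 3 (0.045), HSC-enriched replicate 1 (0.037) or HSC-enriched replicate 4 (0.049). Glycolysis genes rose in 9 of 18 cases and fell in 2 (adjusted p = 0.098, median 0.39), with Pfkm and Eno2 2.64-fold and 2.63-fold higher, Hk3 and Slc2a3 5.17-fold and 2.16-fold lower, and Pkm (-0.12) and Ldha (0.29) not passing, the latter except with quantile normalization (0.39, adjusted p = 0.032). Without Lin+ replicate 3 the list's adjusted p was 0.045.

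Genes of DNA methylation and Polycomb complexes rose in 9 of 24 cases and fell in 3 (adjusted p = 0.116, median 0.17). Dnmt3b, a de novo methyltransferase gene, rose 4.34-fold and Cbx6 2.82-fold, Ezh2 and Uhrf1 fell by 0.68 and 0.60, and Dnmt1 (0.15) and Eed (-0.06) did not pass. Niche adhesion genes rose in 7 of 16 cases and fell in 4 (adjusted p = 0.511, median 0.19), with Esam and Jam3 higher by 2.09 and 1.91, Cxcr4, the receptor gene of Cxcl12, and Selplg lower by folds of 3.62 and 2.30, and Cd47 (-0.06) and Itgav (-0.20) not passing. Notch genes rose in 4 of 15 cases and fell in 4 (adjusted p = 0.887, median 0.07), with the target genes Hes1 and Hey1 5.59-fold and 4.62-fold higher, Notch1 and Dtx1 2.13-fold and 1.99-fold lower, and Notch2 (-0.38) and Rbpj (0.07) not passing, though Notch2 passed without Lin+ replicate 1 (-0.45, adjusted p = 0.042) and with the filter at the median. Gimap genes rose in 4 of 8 cases and fell in 3 (adjusted p = 0.687, median 0.33, mean 0.00), with Gimap5 and Gimap6 higher by 1.48 and 1.22, Gimap3 and Gimap4 lower by folds of 3.82 and 2.82, and Gimap9 (-0.18) not passing.

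DNA repair genes rose in 4 of 22 cases and fell in 7 (adjusted p = 0.851), with a median of 0.06 against a mean of -0.08 and a test direction of lower. Xrcc5 rose 3.44-fold and Atm by 0.87, Lig4 fell 6.40-fold and Brca1 by 1.02, and Lig1 (-0.06) and Parp1 (0.30) did not pass. The Brca1 call was lost without HSC-enriched replicates 3 and 4 together (-0.64, adjusted p = 0.061). Antioxidant genes rose in 4 of 17 cases and fell in 3 (adjusted p = 0.687), with a median of 0.04 against a mean of -0.20 and a test direction of lower. Hmox1, which degrades haem, fell 11.3-fold and Gsr 3.92-fold, Nqo1 and Txnrd1 rose by 0.80 and 0.79, and Gpx1 (-0.29) and Txn1 (-0.14) did not pass. Oxidative phosphorylation genes rose in 2 of 36 cases (Sdhc by 0.41, Ndufa10 by 0.37) and fell in 1 (Ndufa1 by 0.78), with adjusted p = 0.918, a median of 0.03, and Cox4i1 (0.02) and Atp5b (0.13) not passing. The Sdhc call was lost with centring and without any 1 of Lin+ replicates 1, 2 and 4 and HSC-enriched replicates 1, 2 and 3 (0.34 to 0.42, adjusted p = 0.079 to 0.119 over these settings), and all 3 calls were lost without HSC-enriched replicates 3 and 4 together (adjusted p = 0.057 to 0.085). Stromal and osteoblast genes rose in 1 of 15 cases (Pdgfrb, 0.40) and fell in 2 (Cxcl12, -0.53, and Adipoq, -0.48), with adjusted p = 0.687, and Sparc (1.07) and Col3a1 (-0.13) did not pass, though Sparc did without HSC-enriched replicate 2 (1.52, adjusted p = 0.0049). The Pdgfrb call was lost without any 1 of Lin+ replicates 1, 2 and 4 and HSC-enriched replicates 1, 3 and 4 (0.32 to 0.42, adjusted p = 0.054 to 0.106), and that of Cxcl12 without Lin+ replicate 2, HSC-enriched replicate 3 or HSC-enriched replicate 4 (-0.51, -0.46 and -0.45, adjusted p = 0.058, 0.063 and 0.057). Without HSC-enriched replicates 3 and 4 together, Pdgfrb, Cxcl12 and Adipoq all lost their calls. The median of the stromal list was -0.01, its mean 0.02 and the test direction lower, and the group means of Pdgfrb and Adipoq lay at or under the background guide. Reference genes rose in 2 of 9 cases (Rplp0 by 0.59, Tbp by 0.32) and fell in 0 (adjusted p = 0.245, median 0.27), with B2m (0.26) and Actb (-0.17) not passing, and the call of Tbp was lost in 12 alternatives (adjusted p = 0.055 to 0.252), among them leaving out any 1 array except Lin+ replicate 4. B2m passed in 4 alternatives (adjusted p = 0.0029 to 0.049). Of 4 sex-linked genes, Xist rose by 0.78 to 11.23 ± 0.19 while Uty (3.03) and Kdm5d (2.71), of the Y chromosome, stood at background in both groups (list adjusted p = 0.521, median 0.13). Adjusted over the list alone, the members higher and lower numbered 9 and 2 for megakaryocytes, 11 and 5 for TGF-beta and BMP, 9 and 2 for glycolysis and 11 and 5 for DNA methylation and Polycomb. The corresponding pairs were 7 and 5 for adhesion, 4 and 5 for Notch, 4 and 3 for Gimap, 5 and 7 for DNA repair and 5 and 4 for antioxidant genes. They were 0 and 1 for oxidative phosphorylation, 0 and 2 for stromal, 3 and 0 for reference and 1 and 0 for sex-linked genes.

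**Figure D3:**
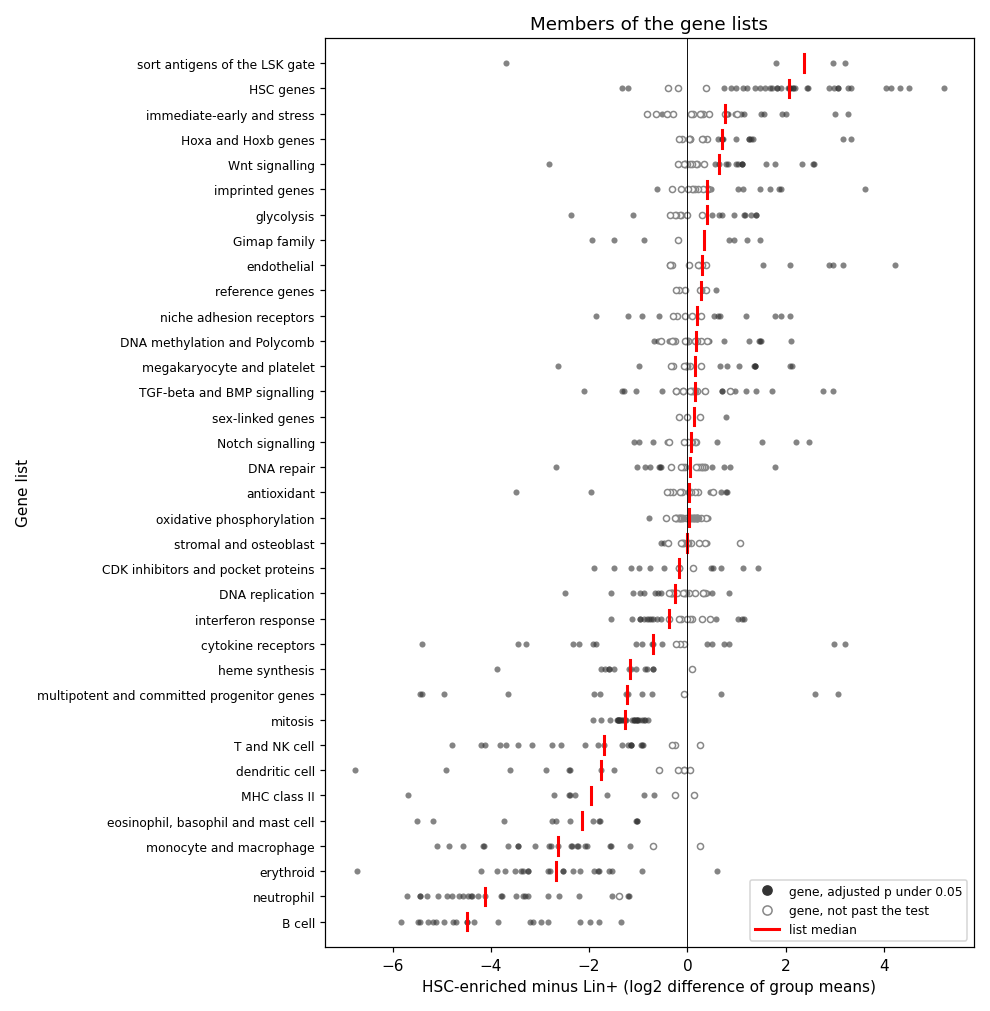
Log2 difference (HSC-enriched minus Lin+, horizontal axis) of each measured member of the 35 gene lists (vertical axis, ordered by median), with filled points for genes with adjusted p under 0.05, open points for the others and a red bar for the list median. Medians run from -4.48 (B cell) to 2.38 (sort antigens of the LSK gate).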

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

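The splits of the samples, the test of endothelial cells and the tests of an array-wide scale were set down before their results were seen. The tests of carry-over and of a wrong label were chosen only after the results were seen. Of the 35 splits of the 8 arrays into 4 and 4, 1 (the real one) gave as many genes higher (3716) or lower (2969). The same held for genes at least 2-fold higher (1153) or lower (1461), and the highest other split called 1 gene in each case. This argues against chance for these counts at a share of 1 in 35, the lowest that 35 splits can give, but does not exclude it. Every other split mixes the groups, so the gap to 1 gene is no further measure of chance. The share also takes the arrays as exchangeable, though the labels do not say that the samples came from separate animals. For gene lists the same count does not argue against chance: 17 of the 35 splits called as many lists one way as the 7 called higher. As many as the 14 called lower were called by 5 splits, with 15 the highest other value. The other splits behind these counts all set 3 arrays of one group with 1 of the other, which keeps part of the difference between the groups, so these counts do not show that chance gives as many lists either. Each other split was counted by the larger of its 2 directions. In the 16 splits of 3 with 1 this was 10 to 15 lists, always those lower in HSC-enriched cells. The count of 17 therefore does not measure chance for the 7. The 18 splits with 2 arrays of each group, which balance that difference, called at most 4 lists one way, against 7 and 14.

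HSC-enriched replicate 3 carried more transcripts of mature lineages than replicates 1 and 2. Median excesses were 2.09 (log2) for the neutrophil list, 0.97 for B cells, 0.59 for monocytes, 0.27 for T and NK cells, 0.26 for erythroid cells and 0.13 for eosinophils, basophils and mast cells. The erythroid excess is smaller than the median difference between replicates 1 and 2 themselves, which was -0.32, so it is within the spread of the arrays it is measured against. Genes dim in both groups had a median excess of 0.0105, so the excess was not shared by dim genes at large. That value cannot decide on an array-wide change of scale. Normalization had left the array medians at 5.22 to 5.33, which holds such a value near 0. A wrong label is argued against by the HSC genes, at 0.963 on a scale with Lin+ at 0 and replicates 1 and 2 at 1. Carry-over of Lin+ cells of all lineages cannot be told apart from other sources: 5 of 6 lists exceeded the upper percentile set for random lists matched on level, but the median of the eosinophil list, whose genes averaged 4.59 on this array, exceeded only 89.2% of them. That list's mean excess was 0.36, 10 of its 12 genes were above the mean of replicates 1 and 2, and its genes brightest in Lin+ cells went with carry-over, Prg2 at 6.00 against 4.43 and 3.85 and Mcpt8 at 5.86 against 4.29 and 4.55. The lineage-negative gate should remove such cells. The excess was set against the Lin+ signal for some genes only. These were at least 8-fold lower in HSC-enriched cells, with a mean on replicates 1 and 2 at or under the background guide. Median shares ran from 1.69% (T and NK, 6 genes from -1.02% to 3.90%) to 5.67% (neutrophil, 7 genes from 3.18% to 9.80%). Brighter genes were left out, such as S100a8, at 12.35 on this array against 12.70 ± 0.07 in Lin+ cells. The shares therefore do not describe the whole lists. No biological explanation was tested.

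HSC-enriched replicate 4 carried an excess of neutrophil transcripts, with a median of 2.03 over the list. Its S100a8 and Ngp levels were 12.50 and 11.98, against 10.34 and 8.64 on replicate 1. Dim genes had a median excess of 0.0508, which cannot decide on an array-wide change of scale either, since normalization holds such a value near 0. Carry-over of Lin+ cells of all lineages is argued against by the other lists. Only 1 of 6, the neutrophil list, stood above the upper percentile set for matched random lists. Carry-over of neutrophils, which the gate should remove, cannot be told apart from other sources, since its test, on the list that showed the excess, could only restate it. All 27 genes of the list were above the mean of replicates 1 and 2, although Mpo, at 5.45, lay below replicate 2 (5.52). Whether the excess came as cells or as free RNA was not tested. The implied share was 3.62% of the Lin+ neutrophil signal, as the median of 7 genes that ran from 0.158% to 13.3%. These were picked by the rule used for replicate 3, which left out brighter genes. S100a8, left out, was at 12.70 ± 0.07 in Lin+ cells, so the share does not describe the whole list. No biological explanation was tested.

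Endothelial genes such as Emcn, Tie1, Eng, Robo4 and Esam were higher in HSC-enriched cells, and endothelial cells in the gate could bring them. Of 8 genes abundant in vascular endothelium (Cdh5, Kdr, Flt1, Flt4, Stab2, Lyve1, Cldn5 and Ptprb), 0 were higher with adjusted p under 0.05. A positive difference was seen for 5 of them (up to 0.39), and the median difference of the 8 was 0.13. The highest upper 95% bound was 0.99 (Stab2), far below the 4.22 of Emcn. This argues against endothelial cells as the source of a rise of that size, but a smaller share of such cells is not excluded. The HSC-enriched means of Flt1 (4.40), Ptprb (4.64), Cldn5 (4.80) and Lyve1 (4.93) lay under the background guide of 5.10, where a small rise is hard to see. Those of Stab2, Flt4, Kdr and Cdh5 lay above it (5.24 to 5.89). Robo4 and Esam also stand in the HSC list, and Eng is an antigen of the gate by the sample labels. Expression of these genes by the HSC-enriched cells themselves, as the design's groups would give, stays open as a hypothesis.

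Single arrays stood apart from the other 3 of their group in 35 of 426 groups of 4 values tested, where about 21.3 are due by chance. The groups are not independent, since list means hold named genes, so the gap between these counts has no known spread. The rule looks for 1 array apart and misses 2 that deviate together, as HSC-enriched replicates 3 and 4 did in the neutrophil list. The values that follow are the gap to the nearest array as a share of the group's range. On Lin+ replicate 1, Ctla2b (0.928), Tgfbr3 (0.838) and the Gimap list (0.961) were highest. Mpo (0.837), Alas2 (0.985) and the progenitor (0.877), eosinophil, basophil and mast cell (0.915) and antioxidant (0.899) lists were lowest there. On Lin+ replicate 2, Pecam1 (0.858), Cox4i1 (0.839) and Ifi27 (0.832) were highest and the sex-linked list (0.901) lowest. On Lin+ replicate 3, Pcna (0.845) and Gimap6 (0.958) were lowest. On Lin+ replicate 4, Trpc6 (0.836) and Rbpj (0.926) were highest and Gfi1 (0.914) lowest.

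Among HSC-enriched arrays, replicate 1 was highest in the Hoxa and Hoxb list (0.853). Replicate 2 was highest in Myct1 (0.858), Slamf1 (0.876), Nr4a1 (0.898), Axin1 (0.913) and the list of CDK inhibitors and pocket proteins (0.841), and lowest in Hoxa9 (0.842). Replicate 3 was highest in Ifi209 (0.896), Ly6c1 (0.872) and the progenitor (0.830), B cell (0.869) and eosinophil, basophil and mast cell (0.880) lists, and lowest in Igf2r (0.867). Replicate 4 was highest in Thbs1 (0.881) and Dvl2 (0.911), and lowest in Plk1 (0.887), Rtp4 (0.851) and Lig1 (0.852). Outside the named genes, 62 of the 958 unnamed probe sets were at least 2-fold higher in HSC-enriched than in Lin+ cells and 43 at least 2-fold lower.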

How the results depend on the processing

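Most results kept their direction and their side of the threshold, and no result reversed under any alternative. The exception among the main counts is the list test: with an estimated correlation, 2 lists were called higher and 4 lower, against 7 and 14. The estimated correlations ran from -0.152 (sex-linked) to 0.698 (neutrophil). Adjusted p rose also where the estimate was below the preset 0.01, as for the sort antigens (-0.110) and the HSC genes (-0.006). The size of the correlation alone therefore does not account for the lost calls. A call lost with an estimated correlation does not by itself show that the genes of a list are correlated. What else separates these 2 forms of the test was not examined. Over the other settings 5 to 9 lists were called higher and 12 to 14 lower. Leaving out 1 array gave 3233 to 3640 genes higher, 2688 to 2933 lower, 1121 to 1261 at least 2-fold higher and 1446 to 1556 at least 2-fold lower. Centring, quantile normalization, filters, probe set rules, variance model and array weights gave 3476 to 4028 higher and 2685 to 3082 lower, and the share of calls that were higher moved by less than 10 points. Without HSC-enriched replicates 3 and 4, a setting chosen after seeing the data, 3152 genes were higher and 2392 lower, 1320 and 1462 at least 2-fold, and 8 and 12 lists were called.

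No pairing by replicate number was seen, though it is not excluded: deviations of same-numbered arrays correlated at -0.15, 0.06, 0.03 and -0.10. With the number as a replicate block 3379 genes were higher and 2743 lower, 1156 and 1461 at least 2-fold, and 7 and 14 lists were called. Among 3191 values of named genes under alternatives, 3105 kept their call, 51 lost one and 35 gained one, and for lists 588 of 628 kept it, 31 lost one and 9 gained one. Signal near background limits what can be read: 10399 genes lay at or under the background guide in both groups, and 18 of the 1074 olfactory receptor genes passed the test. The causes of the other lost or gained calls were not tested.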

Other observations

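Other gene families were examined after the data had been seen, as sets of at least 6 genes whose symbols share their first letters. Of 520 such families, 15 were enriched among genes at least 2-fold lower and 6 among genes at least 2-fold higher in HSC-enriched cells (one-sided Fisher's exact test against all genes tested, Benjamini-Hochberg over 1040 tests). Genes of a family are not independent, and near-identical copies can share probes. Of all genes tested, 6.08% were at least 2-fold lower and 4.80% at least 2-fold higher. They include 10399 at or under the background guide in both groups. With the filter at the 40th percentile, 1122 of 14816 genes were at least 2-fold higher, against 1153 of 24011 without it. A family of genes above background can therefore look enriched, and no filtered background was tested. Antibody variable segments led, with 80 of 94 heavy chain (Ighv, median -3.34) and 77 of 102 kappa chain segments (Igkv, median -2.64) lower. Of 12 Toll-like receptor genes 9 were lower (adjusted p = 3.6e-07), with Tlr13 at 8.61 ± 0.44 in Lin+ and 3.62 ± 0.54 in HSC-enriched cells and Tlr7 and Tlr9 lower by 3.58 and 3.21 on the log2 scale. C-type lectin genes (Clec, 15 of 34, adjusted p = 8.7e-08), interferon-inducible Ifi genes (11 of 19, adjusted p = 3.6e-07) and Ms4a genes and others starting with Ms (11 of 21, adjusted p = 1.2e-06) were lower too. These counts were the same after centring each array, and with quantile normalization they were the same except that 76 Igkv segments passed.

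In the other direction, zinc finger genes named Zfp were the largest enriched family, with 39 of 372 (10.5%) at least 2-fold higher and 3 lower (adjusted p = 0.00045, 38 higher after centring). How much of the gap to the 4.80% of all genes comes from genes near background was not tested. Tceal genes, relatives of Bex1, were higher in 4 of 7 cases (adjusted p = 0.0095), with Tceal1 at 6.60 ± 0.37 against 4.56 ± 0.31. Fkbp genes, which encode prolyl isomerases, were higher in 5 of 13 cases (adjusted p = 0.013), led by Fkbp11 (2.14) and Fkbp9 (1.86). Guanylate-binding protein genes were higher in 4 of 10 cases (Gbp2, Gbp3, Gbp5 and Gbp7, adjusted p = 0.044), and Gbp9 was lower by 1.11.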
